A study of Mus musculus with 2 samples.

How the data were processed

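CTCF ChIP-seq was measured in 2 samples of embryonic mouse lung at day 14.5, which form 1 group. The 5 deposited lists are narrowPeak files on mm10: 1 per replicate, 1 from pooled reads, and the optimal and conservative lists thresholded by the irreproducible discovery rate (IDR). Per the deposited README, both replicate lists were derived from alignments with 1 shared control file, and the thresholded lists from the pooled and replicate lists. The aligner, the peak caller, and the IDR version and threshold are not given in the sources used here. The signal values were deposited as the peak caller gave them and were not scaled between lists, so ranks and percentiles were taken within a list. Where signals of both replicates are given side by side they are unscaled, with a median ratio of replicate 1 to replicate 2 of 1.23. The deposited −log10 q values, which the narrowPeak format places in a column of their own, stop at a highest value shared by 78.0% of optimal peaks and were not used for ranking. The deposited score was 0 throughout the replicate and pooled lists, and in the thresholded lists it reached 1000; it was not used here. The summit offset was used as deposited, and the p-value column was filled with a placeholder by the authors.

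Sites were the summits of optimal peaks on chromosomes 1 to 19, X and Y. The 10 optimal peaks on other sequences were left out. Sequence came from the GRCm38 patch 6 assembly, whose chromosomes are those of mm10, and genes from GENCODE mouse release M21, with 55413 genes and 1 TSS for each. For random placement, sites were placed 10000 times on non-N bases of their own chromosome. Classes were given in the order promoter, 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. The motif matrix was 20 bases wide and grown from a 9-base seed in 15 rounds. It was learned from the strongest 3000 sites of odd-numbered autosomes, and each round left out the 30% with the lowest scores. Its threshold let 1% of windows shifted by 1 kb pass. Adjacent pairs of motif-bearing sites 20 kb to 500 kb apart were compared with strands permuted within chromosomes.

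The 21 gene lists and 23 gene clusters were fixed before the data were examined. List shares used 21884 protein-coding genes with a unique symbol, Fisher's exact test and Benjamini-Hochberg adjustment over the 21 lists. Of the 33 listed housekeeping genes 32 were matched, and every gene of the other lists was matched. Clusters, with 50 kb on each side, were compared with 10000 random windows of the same length on the same chromosome. The threshold was 0.05, and intervals are 95% Wilson intervals unless stated; they cover counting error only. Named genes followed a rule set beforehand: for each list, the 3 members with the strongest promoter site, of which some are printed, and up to 2 members without one for lists that passed. Some genes that the rule takes are not reported here. The rule also took the nearest TSS of the 10 strongest sites, every cluster, the H19 upstream region, and the genes nearest the 5 most discordant sites each way.

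Peak lists hold no read counts, so depth is unknown. As the replicates share 1 biosample and donor record, their likeness and the spread between them may be only technical.

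The tests were tried on simulated data. The promoter test called 7 of 200 sets without a change and 200 of 200 with 1.2 times the share. Those sets were drawn independently under the same model as the test, so these rates may not carry over to real sites. The motif scan found 85.8% of planted motifs, called 0.831% of windows without one, and gave the right strand for 99.8%. The convergence test called 6 of 100 sets with random strands and 100 of 100 with added convergent pairs. The list test called 2 of 1050 lists with random sites, and 48 of 50 lists in which 60% of 50 genes had a site. Each simulated gene got its site independently, so these rates may not carry over to lists of neighbouring genes. The cluster test called 0 of 230 clusters with uniform sites and 215 of 230 with 4 times the density. Those sites were spread uniformly, which real sites need not be, so this rate does not carry over to the clusters reported: the Foxf1 window, at 4.12-fold, did not pass (unadjusted permutation p = 0.0522).

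Alternatives were the conservative list, the strongest 10000 sites, each replicate left out, the strongest pooled peaks, other promoter windows and TSS sets, other overlap rules, another motif window or consensus, other pair distances, circular shifts and clusters without a flank. Merging overlapping peaks, counting discordant sites by summits within 50 bp, and leaving 8 TGF-beta members out of the signalling list were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.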

Results

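The occupancy of CTCF, a zinc finger protein that binds insulators and the anchors of chromatin loops, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the lungs of mouse embryos of the B6NCrl strain at day 14.5. Lungs of both sexes from several dissections had been pulverised and pooled. The series held 1 group of 2 samples, numbered as biological replicates 1 and 2, and no second condition. Both samples carried the same biosample and donor record, so the spread between them may be only technical. The design therefore asked how well the replicates matched, and where in the genome the shared sites lay. Each replicate list and the list from pooled reads held 300000 peaks. The thresholded lists held 54953 peaks (optimal) and 53112 peaks (conservative). Of the optimal peaks, 54943 lay on chromosomes 1 to 19 and X, and these are the sites described here. Peak lists carry no read counts, so the sequencing depth of each sample is unknown. All positions are on mm10 (GRCm38).

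CTCF occupied largely the same places in both replicates. Among the strongest 54953 peaks of each, 47027 of the 54940 replicate 1 peaks on the assembled chromosomes, or 85.6% (95% Wilson interval 85.3 to 85.9), had their summit in a replicate 2 peak. Random placement within chromosomes gave 0.569% (one-sided permutation p = 1e-04, the smallest that 10000 placements can give). The share was 91.4% among the strongest 10000 peaks and 65.0% among the strongest 100000. Peak signal, the authors' own value for each peak, also ranked the sites alike: across 53741 optimal sites found in both replicate lists, Spearman's rho was 0.942 and Pearson's r of log signal was 0.935. These correlations run across sites, which are not independent replicates, and no p-value was computed. The optimal list had already been thresholded for reproducibility by IDR, so part of this agreement in rank was built in. No matching peak was listed in replicate 1 for 488 sites, nor in replicate 2 for 820. The percentile of a site differed between the replicates by a median of 4.69 points, and by 21.6 points or less at 95% of sites.

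**Figure D1:**
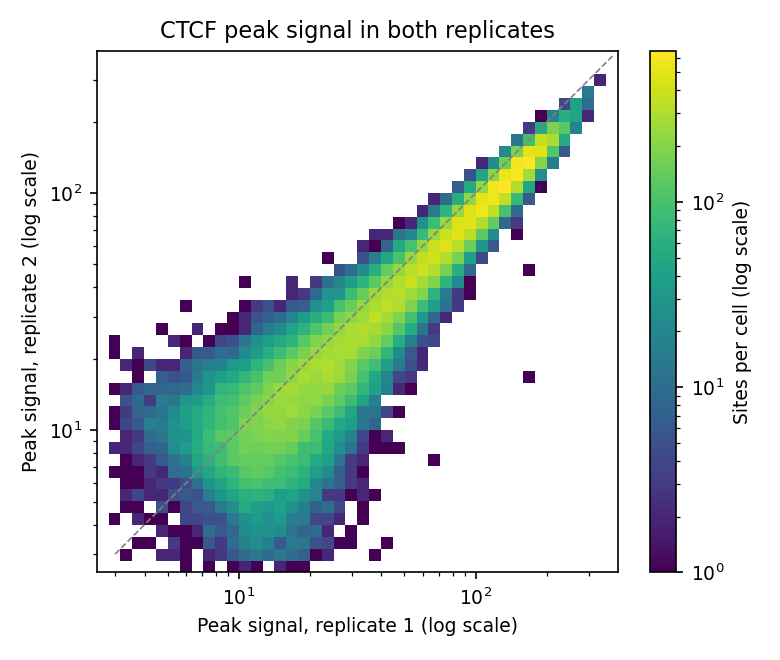
Peak signal at the 53741 optimal sites matched in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, both on log scales in the peak caller's units. Colour gives the number of sites per cell, and the dashed line marks equal values of the unscaled signals, whose median ratio of replicate 1 to replicate 2 was 1.23; the sites gather along a diagonal that is narrow at high signal and broad at low signal (Spearman's rho 0.942).

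Among the 53741 matched optimal sites, those that stood high in 1 replicate and low in the other were rare. The optimal list had already been thresholded for reproducibility, so a low count was largely built in. Peaks outside that list were not screened for such shifts. A single site was in the top 10% of replicate 1 and below the median of replicate 2, and 0 sites showed the opposite, too few for a test of direction. That site lay in an intron, with the nearest TSS that of Fbp2, which encodes a muscle isoform of fructose bisphosphatase, at chromosome 13, 62856242 to 62856710. Its signal in the optimal list was 6.61. The matched signals were 160.6 in replicate 1 and 16.8 in replicate 2, at percentiles 93.7 and 31.9, but the replicate 1 summit with 160.6 lay 238 bp from that of the site. A second replicate 1 summit, 39 bp away, had 52.5, and replicate 2 had a summit with 152.9 at 231 bp. With matching by summits within 50 bp, an alternative added after the data were seen, 0 sites were discordant. The other sites with the largest shifts toward replicate 1 had as nearest genes Gm44313, Muc2, Rasa3 and Gm11949. Those with the largest shifts toward replicate 2 lay nearest Eda2r, Gm30717, Gm7731, Gm12269 and Zc3h12b. Each site took the strongest replicate peak that held its summit, so these shifts can come from a neighbouring peak. The site nearest Gm44313, with a signal of 8.23 in the optimal list, took its replicate 1 signal of 70.1 from the same peak as the overlapping Hist3h2a site.

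The 2 thresholds that the authors deposited gave overlapping sets. Of the optimal sites, 48066 of 54943, or 87.5% (95% Wilson interval 87.2 to 87.8), had their summit in a conservative peak. The conservative list was no subset of the optimal list, as 5033 of its 53112 entries were not in the optimal list and 6874 optimal entries were not in the conservative one. Entries in both had a median signal of 77.1, against 19.96 for entries in the optimal list alone and 19.86 for entries in the conservative list alone.

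CTCF sites were concentrated at genes. Promoters, taken as 1 kb either side of an annotated gene's transcription start site (TSS), held 8069 of 54943 summits, or 14.7% (95% Wilson interval 14.4 to 14.98), against 3.98% under random placement within chromosomes. The enrichment over random placement was 4.59-fold in 5' UTRs, 3.69-fold in promoters, 1.91-fold in coding exons, 1.61-fold in non-coding exons and 1.37-fold in 3' UTRs. Introns held 43.1% of sites against 42.0% expected, and intergenic sequence held 35.2% against 49.9%, a 0.705-fold share. Each of the 7 classes had a two-sided permutation p = 2e-04 after Benjamini-Hochberg adjustment, the smallest that 10000 placements can give. Among the strongest 10000 sites the intron share was 39.3%, below its expected share. Weak sites were at promoters more often than strong ones: 19.3% of the weakest 10% against 12.8% of the strongest 10% (Fisher's exact test, odds ratio 0.611, p = 7.91e-21). The difference, strongest minus weakest, was -6.55 percentage points, and it was -3.71 without replicate 2 and -3.08 with the strongest pooled peaks. Within the strongest 10000 sites alone this difference turned and did not pass the test (2.00 percentage points higher in the strongest 10%, Fisher's exact p = 0.215).

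**Figure D2:**
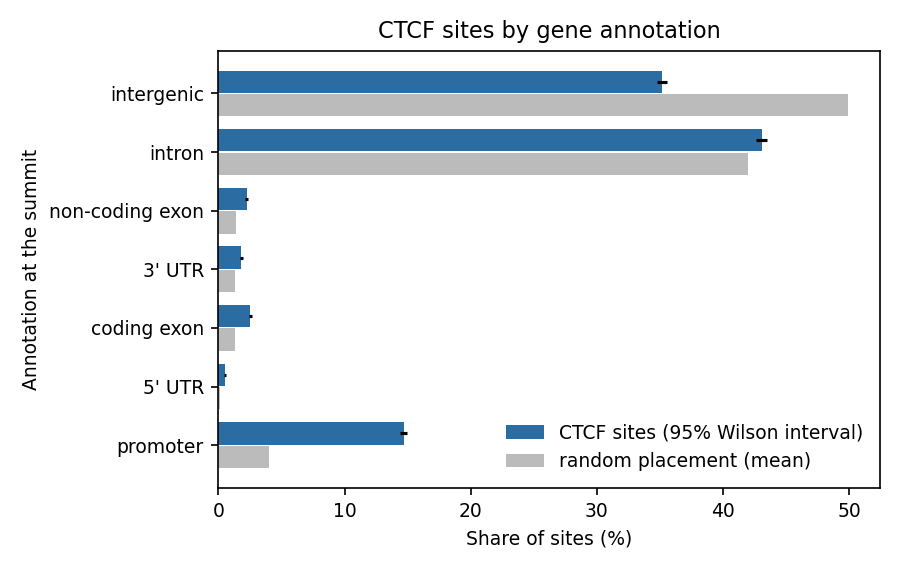
Share of the 54943 optimal sites in each annotation class, in percent, with 95% Wilson intervals (blue), beside the mean of 10000 random placements within chromosomes (grey). Promoters held 14.7% of sites against 3.98% under random placement, and intergenic sequence 35.2% against 49.9%.

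The strongest site of the genome lay between genes 13509 bp from the TSS of Rbm19, an RNA-binding protein gene, at chromosome 5, 120102764 to 120103129. Its signal was 640.7, it ranked 1 in both replicates, and it held the motif CGGCCACCAGGGGGCGCACA on the reverse strand at 120102927 to 120102946. The next site, with a signal of 626.5 and rank 2 in both replicates, lay in an intron, with Fam129b the gene of the nearest TSS, at chromosome 2, 32912446 to 32912785, and held CAACCACTAGGTGTCGCCAT on the reverse strand. The nearest TSSs of the remaining 8 of the 10 strongest sites belonged to Gm7775, Mir7019, Glrx3, Gm43246, Gm44123, Srgap1, Gm5981 and Epm2aip1. Of these 10 sites, 1 was in a promoter, that of the predicted gene Gm43246, 4 were in introns and 5 were intergenic. All 10 held the motif, and all 10 were among the strongest 21 peaks of each replicate.

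The sequence under the sites had the textbook CTCF core. A matrix learned from sites on odd-numbered autosomes had the consensus TGGCCACCAGGGGGCGCTAG. On the even-numbered autosomes and X, 15522 of 25415 sites, or 61.1% (95% Wilson interval 60.5 to 61.7), held a match within 50 bp of the summit, against 0.972% of windows 1 kb away (exact McNemar test, log10 p = -4416.7). Strong sites held the motif far more often: 88.5% of the strongest 10% against 27.7% of the weakest 10% (Fisher's exact test, log10 p = -457.1). Promoter sites held it less often than others, in 1301 of 3537 sites or 36.8%, against 14221 of 21878 or 65.0% elsewhere (Fisher's exact test, odds ratio 0.313, log10 p = -217.0). The promoter comparison was chosen after the data were seen. The gap was present in each 10% step of signal, from 79.8% against 89.8% in the strongest to 10.2% against 31.7% in the weakest. The matrix was learned from the strongest 3000 sites of the odd-numbered autosomes. Part of the differences by signal and at promoters may therefore be built into it, which was not tested.

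**Figure D3:**
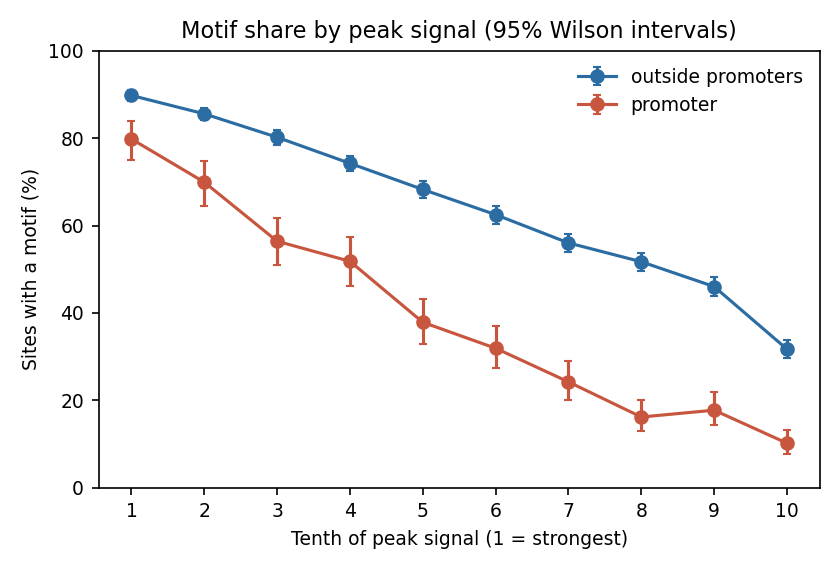
Share of sites with a CTCF motif within 50 bp of the summit, in percent with 95% Wilson intervals, against the decile of peak signal (1 is the strongest), for promoter sites (red) and sites outside promoters (blue) on the even-numbered autosomes and X. In the strongest decile the shares were 79.8% and 89.8%, and in the weakest decile 10.2% and 31.7%.

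Neighbouring motifs faced each other more often than chance. The motif has a direction, and convergent pairs, in which both motifs point into the interval between them, are the textbook arrangement at loop anchors. Among 19004 pairs of adjacent motif-bearing sites 20 kb to 500 kb apart, 27.2% were convergent (95% Wilson interval 26.6 to 27.9), 22.4% divergent and 50.4% in tandem. Permuting strands within chromosomes gave 24.999% convergent (two-sided permutation p = 2e-04, the smallest that 10000 permutations can give). Between 100 kb and 1 Mb the convergent share was 32.1% of 5823 pairs. Over all 33551 pairs up to 2 Mb apart, which take in close neighbours, the direction turned, with 24.1% convergent (permutation p = 2e-04).

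Repeats held fewer sites than their share of the genome. Of the 54943 summits, 19.6% (95% Wilson interval 19.2 to 19.9) lay in soft-masked sequence, against 33.6% under random placement (two-sided permutation p = 2e-04, the smallest possible). Among the strongest 10000 sites the soft-masked share was 5.68%. The masking marks repeats of every kind, and single repeat families were not analysed here. Random placement used all non-N bases, and whether reads could be placed uniquely in repeats was not examined. The lower share can therefore not be read as avoidance of repeats by CTCF.

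Clustered protocadherins, the neuronal adhesion genes whose alternative promoters are a textbook CTCF target, had the highest share of promoters with a site among the 21 gene lists fixed before the data were examined. A site lay within 1 kb of the TSS in 35 of 55 members, or 63.6% (95% Wilson interval 50.4 to 75.1), against 26.5% of other protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 6.30e-08). The strongest were at Pcdhac1, with a signal of 156.0 at chromosome 18, 49 bp upstream of its TSS, and at Pcdhgc3 (139.4) and Pcdhgb7 (137.9). Pcdha1 and Pcdha3 had none. The members lie together on chromosome 18 and Fisher's test takes them as independent, so its p-value may be too small. By number of sites, neither protocadherin cluster passed (permutation test, adjusted p = 0.635 for alpha and 0.60 for beta and gamma). None of the 55 had a site among the strongest 10000, against 4.28% of other genes, so at that threshold the list had a lower share without passing the exact test (adjusted p = 0.526).

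Cytosolic ribosomal protein genes, whose products build the ribosome, also had more promoter sites, in 39 of 83 members or 47.0% against 26.5% of other genes (Fisher's exact test, adjusted p = 0.000437). The other genes were not matched for promoter base composition in this or any other list test. How far composition contributes to the higher shares was not tested. The strongest sites of ribosomal protein genes were among the strongest of the genome. Rpl26 had a signal of 386.2, with its summit 116 bp upstream of the TSS on chromosome 11. Rplp0 had 379.6 and Rpl5 had 365.0, and Rpl10l and Rpl12 had no site. Genes of FGF, SHH, WNT and BMP signalling, the pathways that shape the branching lung, listed together with genes of TGF-beta signalling, had a site in 23 of 51 members, or 45.1% against 26.5% (Fisher's exact test, adjusted p = 0.0172). The strongest were at Tgfb3 (352.2), Wnt7b (336.4), which encodes a WNT ligand of the lung epithelium, and Ltbp1 (236.5), which binds latent TGF-beta. Bmp2 and Bmp4 had none. Without 8 members of TGF-beta signalling, among them Tgfb3 and Ltbp1, the list did not pass, with 18 of 43 or 41.9% (exact test, adjusted p = 0.0966), a split chosen after the data were seen. The call was also lost without replicate 1: in the strongest peaks of replicate 2 alone the share was 41.2% (exact test, adjusted p = 0.0638). It was lost as well among the strongest 10000 sites (9.80% against 4.26% of other genes, exact test, adjusted p = 0.276), where the odds ratio was 2.44, against 2.27 among all sites.

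Sensory receptor genes almost lacked promoter sites. Olfactory receptors, expressed in the nose, had a site in 7 of 1091 members, or 0.642% (95% Wilson interval 0.311 to 1.32), against 27.9% of other genes (Fisher's exact test, adjusted p = 1.79e-135). The strongest of the 7 was at Olfr557 (207.5), followed by Olfr156 (151.2) and Olfr658 (120.9), while Olfr1 and Olfr10 had none. Vomeronasal receptors had a site in 0 of 325 members, with an upper Wilson limit of 1.17%, against 27.0% (Fisher's exact test, adjusted p = 1.42e-43). Vmn1r1 and Vmn1r10 were among them. Fisher's test takes genes as independent, which neighbouring members of a receptor family need not be, so these p-values may be too small.

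The other 16 lists did not pass Fisher's exact test after adjustment. Markers of lung mesenchyme and mesothelium had a site in 16 of 38 members (exact test, adjusted p = 0.0966), with the strongest at Col1a1 (334.9), a fibrillar collagen, and Gli1 (305.9), a target of hedgehog signalling. Tbx3 had 199.6. Markers of lung epithelium had 12 of 42 (exact test, adjusted p = 0.766), led by Muc1 (328.6), Elf3 (277.5) and Abca3 (264.6), a lipid transporter of surfactant. The CTCF and cohesin genes had 8 of 17 (exact test, adjusted p = 0.168), led by Esco1 (218.1), Smc3 (191.1) and Pds5b (135.5). With conservative sites the share was 58.8%, which passed (exact test, adjusted p = 0.0148), as it did without replicate 1 (adjusted p = 0.0233). Imprinted genes passed without replicate 2 (43.75%, exact test, adjusted p = 0.0497). Retinoic acid and Notch genes passed with a 5 kb window (71.4%, exact test, adjusted p = 0.0234) and with all transcript starts (57.1%, adjusted p = 0.0471). Histone genes passed, with a lower share than other genes, with the strongest pooled peaks (13.2%, exact test, adjusted p = 0.0440) and with all transcript starts (14.7%, adjusted p = 0.00221). Imprinted genes had 17 of 48, led by H13 (409.9), Blcap (251.2) and Peg10 (156.2). Cell cycle genes had 15 of 38, led by Mcm5 (263.4), and retinoic acid and Notch genes 11 of 28, led by Jag1 (234.8). Hox genes had 7 of 39, led by Hoxa7 (385.0) and Hoxb5 (314.7). Housekeeping genes had 10 of 32, led by Actb (133.8), and genes with KRAB-type zinc finger names 123 of 391, led by Zfp90 (313.2). Histone genes had 10 of 68, led by Hist1h4j (245.3). Markers of tissues or cells other than lung epithelium and mesenchyme had sites in 4 of 18 members for smooth muscle, 5 of 28 for endothelium, 4 of 32 for blood, 3 of 22 for heart, 1 of 20 for liver and 4 of 24 for neurons. The strongest sites were at Myh11 (210.8) for smooth muscle, Nrp1 (200.6) for endothelium, Ryr2 (176.9) for heart, Apoh (29.7) for liver and Elavl4 (196.1) for neurons.

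**Figure D4:**
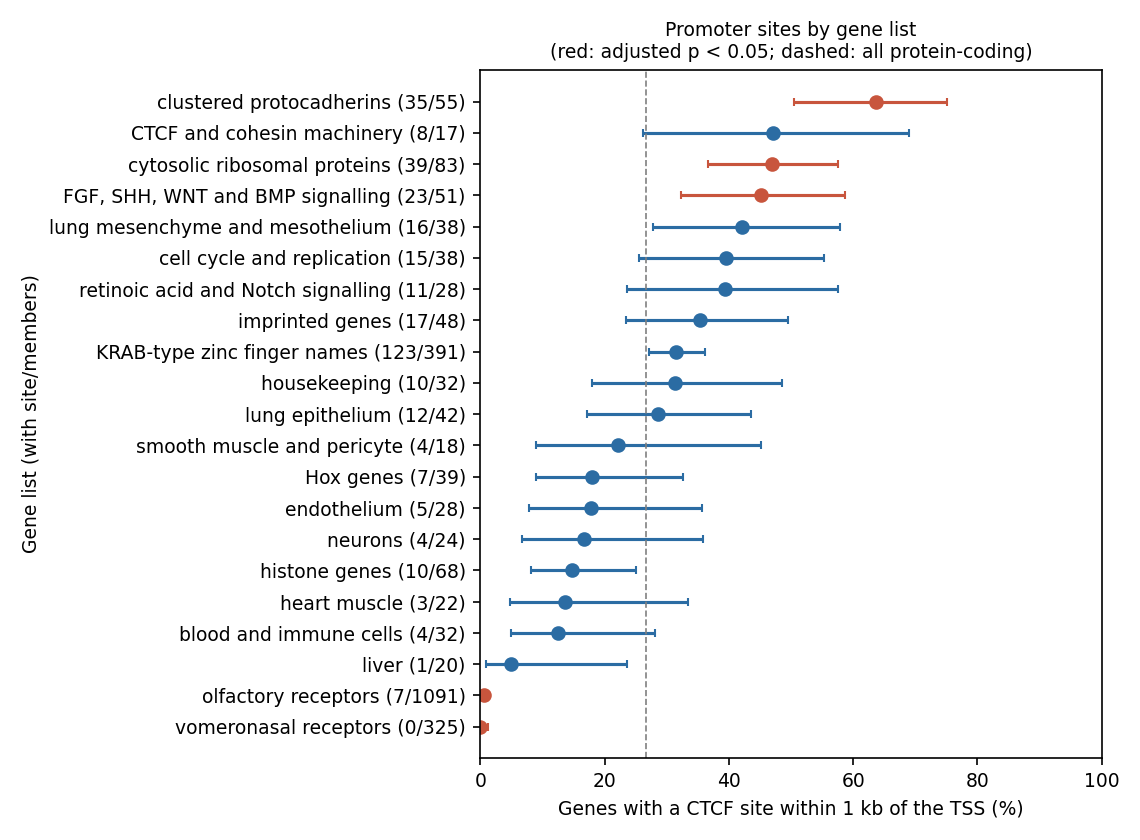
Share of each list's protein-coding members with an optimal CTCF site within 1 kb of the TSS, in percent with 95% Wilson intervals; the counts stand beside each name and the dashed line marks all protein-coding genes. The lists in red passed Fisher's exact test after adjustment, from clustered protocadherins at 63.6% to vomeronasal receptors at 0 of 325.

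None of the 23 gene clusters fixed beforehand differed in its number of sites from random windows of equal length on its chromosome after adjustment (permutation test, two-sided; 0 of 23 at an adjusted p of 0.05). The protocadherin beta and gamma cluster came nearest, with 43 sites against a mean of 12.9 (unadjusted permutation p = 0.0374, adjusted p = 0.60). The window of Foxf1, a transcription factor of the lung mesenchyme, held 14 against 3.4 (unadjusted permutation p = 0.0522). HoxB held 24 sites and HoxA 11, the strongest of HoxA at a signal of 385.0. The alpha globin window held 10 and the beta globin window 2. The surfactant protein A and D window held 5, each with a motif, the Nkx2-1 window 8, and the Shh window 14. The windows of Fgf10 and Sox9 held 1 each. HoxC held 6, HoxD 9, protocadherin alpha 11, Kcnq1 22, Grb10 16, Tbx4 and Tbx2 14, Myc 6 and Mycn 4. The Dlk1 and Meg3 window held 11, and the histone cluster on chromosome 13 held 36. The Snrpn window held 4 sites against a mean of 26.1.

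The region around H19 and Igf2, imprinted genes that share enhancers, held 15 sites against a mean of 4.90 in random windows (unadjusted permutation p = 0.131). In the known imprinting control region, 2 to 4.5 kb upstream of the H19 TSS on chromosome 7, there were 3 intergenic sites. Their summits lay 2165, 2625 and 3676 bp upstream, at 142580308, 142580768 and 142581819. Signals were 145.0, 140.1 and 124.7 in the optimal list, and ranks in the replicate lists ran from 13375 to 16691. None of the 3 reached the motif threshold of 10.8 bits, their best scores being 4.01, 8.52 and 3.82 bits. The matrix was learned from the strongest sites, so these scores do not show that every form of the motif is absent.

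The X chromosome had far fewer sites than any autosome. It carried 1275 sites, or 7.80 per Mb of sequence, against 17.2 to 34.6 per Mb on the autosomes, with a median of 22.9. The ratio of X to the median autosome was 0.341 (95% Poisson interval 0.323 to 0.361). Among the strongest 10000 sites it was 0.0823. The densest chromosome was 11, and chromosome Y had 0 sites in the optimal list. Of the non-N sequence of Y, 96.3% was soft-masked, against 46.8% on X. Unique placement of reads there was not examined, so the 0 cannot be read as absence of CTCF from Y. X was set apart beforehand because the tissue came from both sexes, and males carry X at fewer copies than autosomes. How far copy number lowers the count on X was not tested. No test was made, as chromosomes are not replicates.

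**Figure D5:**
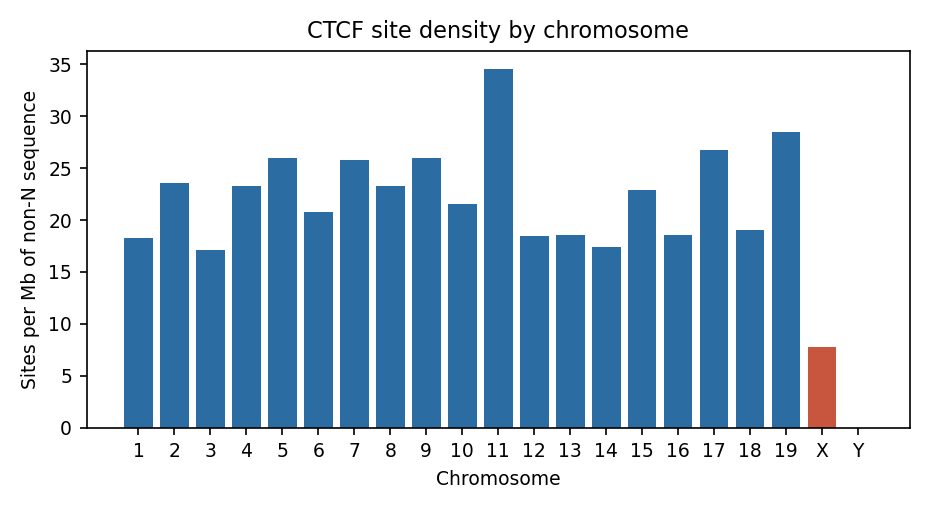
Optimal CTCF sites per Mb of non-N sequence (y axis) on each chromosome (x axis), autosomes in blue and sex chromosomes in red. X had 7.80 sites per Mb, below the lowest autosome at 17.2. Y, whose non-N sequence was 96.3% soft-masked, had 0 sites.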

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

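Chosen only after the results were seen were the tests of motif occupancy and repeat content on X, of signal at promoter sites, and of receptor motif occupancy and sequence uniqueness, and the scan of peaks outside the optimal list. Among pooled peaks outside the optimal list, 7.27% held the CTCF motif, against 0.816% of windows 1 kb away, with 29.1% in the strongest decile and 1.95% in the weakest. Among replicate 1 peaks outside the optimal list the share was 5.72% against 0.754%, with 22.6% and 1.40% in those deciles. Among replicate 2 peaks outside it the share was 5.15% against 0.712%, with 21.5% and 1.14%.

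The X chromosome carried 0.341 times the site density of the median autosome. At equal motif score, the share of motif instances with a site on X was 0.625 times that on autosomes (95% bootstrap interval 0.591 to 0.660), which argues against a shortage of motifs as the whole cause. The test set first, motif instances per Mb on X over the median autosome, gave 0.701 (0.685 to 0.717), which did not clear its bounds of 0.45 and 0.7. Over sequence that was not soft-masked the density ratio was 0.427 (0.401 to 0.454), which argues against repeat content as the whole cause. Motif-bearing X sites had 0.704 times the signal of autosomal sites of equal motif score (0.656 to 0.765). Lower signal at X sites may therefore account for part of the shortage. The lower copy number of X in the males was not separated from this, and no biological explanation was tested.

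Promoter sites held the motif in 36.8% of cases, against 65.0% elsewhere. Within deciles of signal the mean difference was 24.99 percentage points (95% bootstrap interval 23.4 to 26.7), which argues against weaker signal as the whole cause. With a motif search 150 bp either side of the summit, the background-corrected difference was 0.978 times that at 50 bp (0.953 to 1.00), which argues against misplaced summits. At equal GC content the difference was 14.4 points (12.1 to 16.8), so base composition may account for part of it and not the whole. The matrix was learned from the strongest sites, and how far that shapes the difference was not tested. No biological explanation was tested.

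Olfactory and vomeronasal receptor promoters had a site in 7 of 1416 genes, or 0.494%. Other genes of the same GC content and CpG ratio, found for 1263 of the 1416 receptors (89.2%), had one in 1.02% (0.552 to 1.58 over 1000 draws), so the base composition of receptor promoters may account for most of the pattern among the matched receptors. A motif lay near 3.39% of receptor TSSs against 20.8% of others, a ratio of 0.163 (0.121 to 0.21, the test set first, with a bound of 0.2), so a lack of motifs may account for part of the pattern, while the motif instances present had a site at 0.246 times the rate at other TSSs at equal score (0.0529 to 0.470, 5 of 51 instances), which argues against it as the whole cause. Among 830 receptors with nearly all of the promoter sequence unique, 0.482% had a site (0.188 to 1.23). This argues against non-unique sequence for the receptors covered, which were 731 of 1091 olfactory and 99 of 325 vomeronasal receptors. In vomeronasal promoters 61.3% of 32-mers were unique, against 89.7% in olfactory ones. For most vomeronasal receptors this test can therefore not decide. The test set first, the share of unique 32-mers over both families, gave 0.832 (0.818 to 0.845) between its bounds of 0.5 and 0.9. No biological explanation was tested.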

How the results depend on the processing

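Chosen after the results were seen were the merging of overlapping peaks, the matching of discordant sites by summits, the signalling list without TGF-beta members, and the bin of pairs 1 kb to 20 kb apart. The promoter share, the motif share and the soft-masked share kept their direction and passed their tests under every alternative run for them, and without either replicate the promoter share was 14.8% to 14.9%. Without either replicate the X density ratio was 0.330 to 0.344. Replicate overlap, rank correlation and discordance need both replicates, and the optimal and conservative lists cannot be split by replicate, so none of these has a value without 1 of them. No paired analysis was possible because the series has 1 group.

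With the strongest 10000 sites, 3 lists passed in place of 5 and the X density ratio was 0.0823. There the intron share turned to 39.3%, below expectation, and the promoter difference by strength to 2.00 percentage points. List shares also changed side of other genes for imprinted genes (4.17%), smooth muscle (5.56%), housekeeping genes (0%), Hox genes (12.8%), clustered protocadherins (0%) and KRAB-type names (2.56%). The protocadherin alpha window held 0 sites and the histone cluster 11, each now on the other side of its random mean. The number of lists was 6 with the conservative list (CTCF and cohesin added), the strongest pooled peaks (histone genes added) and the 5 kb window (retinoic acid and Notch added), and 7 with all transcript starts (histone genes and retinoic acid and Notch added). It was 4 without TGF-beta members, as the signalling list did not pass. Without either replicate it was 5 to 6, with imprinted genes added without replicate 2, and without replicate 1 the CTCF and cohesin list passed in place of the signalling list. Lung epithelium turned with the conservative list (21.4%) and the strongest pooled peaks (26.2%). With a 5 kb window smooth muscle (61.1%), heart (45.5%), neurons (58.3%) and Hox genes (61.5%) turned, as did smooth muscle with all transcript starts (44.4%). Without either replicate smooth muscle was 27.8% to 33.3%, housekeeping genes 25% to 31.25% and HoxC 5 to 6 sites. The Kcnq1 cluster without a flank held 9 sites. Pairs up to 2 Mb apart were convergent in 24.1%, a turn that the added close pairs show, as 19.1% of pairs 1 kb to 20 kb apart were convergent. With summits within 50 bp 0 sites were discordant, in place of 1, as the replicate peaks at the Fbp2 site have separate summits. The rank correlation was 0.948 with summits within 50 bp and 0.962 with conservative sites. For the other changes the cause was not tested. Depth is unknown, so how far depth limits weak sites cannot be given.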

Other observations

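The splits described here were chosen after the results were seen. Among clustered protocadherins a promoter site was found at 19 of 21 gamma genes, 6 of 12 alpha genes and 10 of 22 beta genes. The motif was found at 4 of the alpha sites, 2 of the beta sites and 0 of the gamma sites.

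The convergent share of neighbouring sites was 20.4% of 852 pairs up to 1 kb apart, 19.1% of pairs 1 kb to 20 kb apart, 25.4% at 20 kb to 100 kb, 31.8% at 100 kb to 500 kb and 35.8% at 500 kb to 2000 kb. Of 162217 motif instances in the genome, 21.2% had a site. The share was 32.7% in promoters and 18.7% in intergenic sequence, and 10.5% in soft-masked sequence against 33.5% elsewhere. These shares were not matched for motif score. Of instances in the highest decile of motif score, 72.8% had a site, with 50.2% in soft-masked sequence and 86.2% elsewhere. Whether reads could be placed uniquely in repeats was not examined. The lower shares in soft-masked sequence can therefore not be read as lower occupancy by CTCF.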
